A study of Mus musculus with 8 samples.

How the data were processed

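Total RNA in 8 liver samples from male mice, 4 at age 8 weeks and 4 at 80 weeks, was measured 8 h after acetaminophen on 8 single-colour Agilent arrays, each with 62976 spots. The dose, the mouse strain and whether each array held a separate animal were not given in the sources used here, so p-values measure the spread between these samples, which may be technical. The 8 arrays lay on 1 slide and were read in 1 scan, per the file headers. The 8-week samples took row 1 of the slide and the 80-week samples row 2, so row and age cannot be told apart.

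The scanner files hold spot intensity values that Feature Extraction 10.7.3.1 had background-corrected before the authors deposited them, per the file headers, whereas the submitters' processing notes name Agilent Feature Extraction 9.1. The authors' deposited table of intensity values, described as normalized, matched the scanner's processed signal within 1% for 100% of 56605 non-control probes on every array, so it carried no scaling between arrays. Its column medians ran from 14.2 to 28.1. It was used only as an alternative, and it held 0 columns from other samples.

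From the scanner's processed signal, the values were taken as log2, spots marked as outliers by the software were left out (59 to 97 per array), spots of one probe were averaged, and each array's 75th percentile over the non-control probes was subtracted. That percentile ran from 154.7 to 352.8 intensity units and the share of probes well above background from 43.3% to 50.4%. No spot was saturated. A probe was tested when it was well above background on at least 4 of the 8 arrays, and a gene was represented by its brightest tested probe, which left 17565 genes. Of these, 13977 matched a symbol in the RefSeq gene table of mouse assembly GRCm38.p6, used for names only, and 3588 kept the array's own name. Probe positions are those of the array files, on build mm9.

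Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The only comparison was 80-week against 8-week livers. Untreated livers were not analysed here, so a difference between ages at rest and an age-dependent drug response cannot be told apart. A set of 44 gene lists, covering drug metabolism, stress, inflammation, zonation, metabolism and cell types, was tested with camera at a preset correlation of 0.01, adjusted over the lists. The number of arrays limits the precision. A gene above background on no array of one group is given only as a bound: the brighter group's mean against the dimmer group's mean of, per array, the higher of the gene's own value and the lowest value among probes well above background. Such a bound, written as "at least", allows for the dim signal but not for sampling error.

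The comparison, its tests, the gene lists and the naming rule were fixed before the data were examined, and the tests of possible causes chosen later are named as such where they are given. Named genes are the 12 largest positive and 12 largest negative log2 differences among genes past the threshold that had an official-looking symbol and no overlap between groups, up to 4 members of each list with the smallest p, and 15 genes of drug metabolism, stress, inflammation and growth. The rule gave 194 genes, of which the text names 58, and the effect of each alternative and the search for outlying samples were computed for those 58. On simulated data with the real means and spreads, for this comparison over 17565 genes, 34% of 50 genes changed 2-fold were recovered. The share was 82% of 50 changed 4-fold, 92% of 50 changed 8-fold and 100% of 50 changed 16-fold. Of 17325 unchanged genes, 10 were called. The simulation drew each gene independently with the same spread on all 8 arrays. It held no outlying array and no correlation between genes, so its rates may not apply to the real arrays.

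The alternatives tried were normexp background correction, quantile and median scaling, other filters on dim probes, the mean of a gene's probes, a trended and robust variance prior, array weights, the replicate number as a block, retained outlier spots, the authors' deposited table, the omission of each array in turn, and set tests with an estimated correlation or with fry. Omitting young replicates 1 and 2 together was added after the data were seen. Normexp was run with an offset of 50 intensity units added to every spot.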

Results

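Liver transcripts were measured 8 h after acetaminophen, a drug whose oxidative metabolite injures the hepatocytes around the central vein, in 4 samples from 8-week male mice (young) and 4 from 80-week male mice (old). Values are log2 intensity relative to each array's 75th percentile, and differences are 80-week minus 8-week. Between 24537 and 28536 probes per array were well above background. Correlations between arrays over the tested genes ran from 0.941 to 0.99 within the young group, from 0.967 to 0.984 within the old group and from 0.921 to 0.983 between groups. The first principal component held 49.1% of the variance and placed young replicates 1 and 2 at -61.3 and -99.2, far from the other 6 arrays. Young replicates 3 and 4, at 10.2 and 12.3, lay next to the old arrays, at 17.0 to 47.5, so the ages did not overlap on this component but the widest gap fell within the young group.

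The comparison asked which transcripts differed between the ages at this time after the drug. Cidea, a lipid droplet protein, showed the largest difference, at 6.27 ± 1.45 in old and -2.70 ± 0.59 in young livers (SD, n = 4 each), a log2 difference of 8.97 (SE 0.64, adjusted p = 0.000752). It was above background on 3 of the 4 young arrays. Jchain, which joins polymeric immunoglobulins, was higher by 5.41 (SE 0.70, adjusted p = 0.0127) and was above background on 1 of the 4 young arrays, so the size of this difference rests mostly on signal not above background. Slc1a2, a glutamate transporter of pericentral hepatocytes, was 20.9-fold higher in old livers (adjusted p = 0.0127). Hspa1b, a gene of an inducible heat shock protein, had a log2 difference of -5.50 (SE 0.81, adjusted p = 0.0241).

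**Figure D1:**
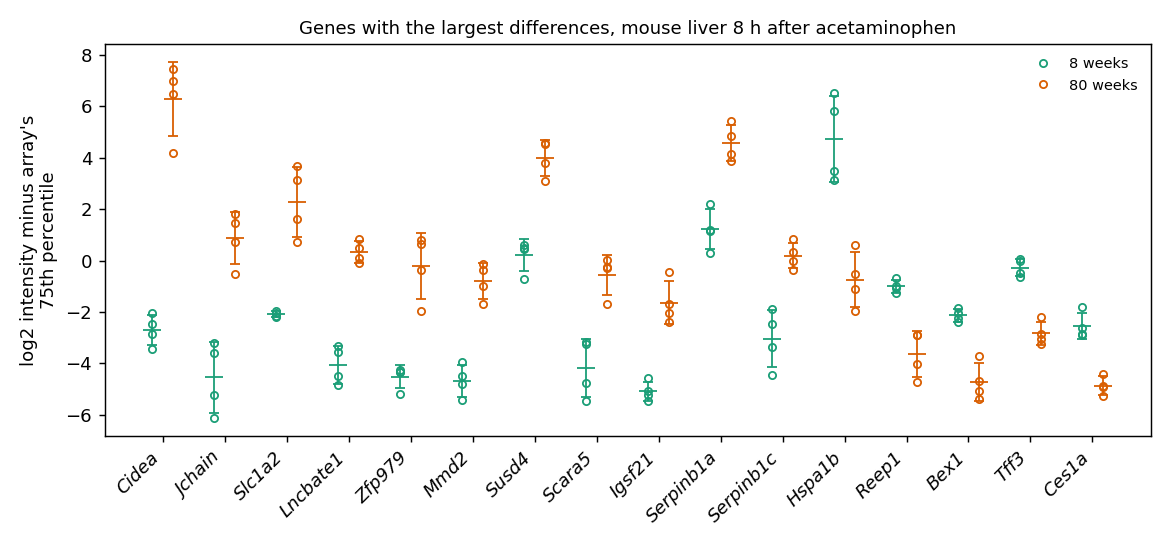
Log2 intensity minus each array's 75th percentile (vertical axis) for the 16 genes named here by size of difference (horizontal axis). Circles are single arrays, and bars show mean ± SD of 4 arrays at 8 weeks (green) and at 80 weeks (orange). The age groups do not overlap for any gene drawn, and Cidea differs by 8.97.

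Of 17565 genes, 58 were higher and 5 lower in 80-week livers, all by at least 2-fold, and 35 and 5 of these had official-looking symbols. At an unadjusted p under 0.05 the numbers were 1390 and 1078. The groups did not overlap for 1472 genes (8.38%), where chance gives 2.86%. Without young replicate 1 the counts were 25 and 2, without young replicate 2 they were 41 and 3, without young replicate 4 they were 69 and 8, without old replicate 2 they were 50 and 14, without old replicate 3 they were 33 and 5, and without old replicate 4 they were 35 and 4. Without young replicates 1 and 2 together, a choice made after the data were seen, they were 12 and 2.

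Susd4, a complement regulator, was 13.9-fold higher in old livers (3.79, SE 0.41, adjusted p = 0.00496), at chromosome 1, 184825726 to 184825785. Serpinb1a, an inhibitor of neutrophil proteases, was 10.2-fold higher (3.36, SE 0.45, adjusted p = 0.0140), and its neighbour Serpinb1c, a close relative, was 9.44-fold higher with 2 of 4 young arrays above background. The genes Lncbate1, Zfp979, Mmd2, Scara5 and Igsf21 were above background on 4 old arrays and on 0 young arrays. They were at least 12.3-fold, 8.41-fold, 5.62-fold, 6.65-fold and 3.14-fold higher in old livers, respectively. Among the 5 lower genes, Tff3, a trefoil factor, had a log2 difference of -2.56 (SE 0.27, adjusted p = 0.00496) and was above background on 2 of 4 old arrays. Reep1, Bex1 and the carboxylesterase gene Ces1a were above background on 0 old arrays and were at least 4.03-fold, 1.88-fold and 1.41-fold lower in old livers. These 8 bounds compare group means and carry no sampling error, so single arrays can differ by less. They are given for the scanner's own background correction only. With normexp each gene's fold fell below its bound under quantile or percentile scaling. The lower folds were 4.15 for Lncbate1, 3.48 for Zfp979, 2.44 for Mmd2, 2.73 for Scara5 and 2.06 for Igsf21. For Reep1, Bex1 and Ces1a they were 1.84, 1.56 and 1.36. The offset of 50 added with normexp by itself makes the folds of dim genes smaller, so this comparison does not test the bounds. Of the 16 genes named here by size, 8 stayed past the threshold with each array left out in turn. Of these 8, Igsf21 (adjusted p = 0.101 and 0.138) and Ces1a (0.184 and 0.332) lost it with normexp background correction under quantile and percentile scaling, and Mmd2 (0.0563) under percentile scaling. Bex1 and Slc1a2 lost it without young replicate 1 or 2, Zfp979 without young replicate 1, Serpinb1a without young replicate 1 or old replicate 3, and Hspa1b, Reep1, Scara5 and Serpinb1c under 5 or 6 of the 8 omissions of 1 array, with highest adjusted p of 0.101, 0.113, 0.132 and 0.127. Only Cidea (adjusted p = 0.0456) and Lncbate1 (0.0314) kept it among these 16 without young replicates 1 and 2, where the log2 difference was 4.38 for Slc1a2, -2.62 for Tff3, 3.45 for Susd4 and -4.07 for Hspa1b, with 2 young arrays left.

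Single genes of acetaminophen handling did not pass the threshold. Cyp2e1, the main enzyme that oxidises the drug, differed by 0.07 (SE 0.24, adjusted p = 0.901), Cyp1a2 by 0.60 (SE 0.48) and Cyp3a11 by -0.15 (SE 0.56). The sign for Cyp2e1 turned under median scaling (-0.03). In the bioactivation list 0 of 11 tested members passed (camera adjusted p = 0.295), in glucuronidation and sulfation 0 of 20 (0.0538) and in glutathione S-transferases 0 of 20 (0.0860). The glucuronidation and sulfation list was past the threshold under 8 of 14 other settings of processing or test and under 4 of the 8 omissions of 1 array (adjusted p from 0.0152 to 0.0484), but not with an estimated correlation (0.764) or with fry (0.542). Glutathione S-transferases were past it under 1 of the 14 and under 2 omissions. The difference for Gclc, which makes the first committed step of glutathione synthesis, was -0.99 (SE 0.33, adjusted p = 0.291), for Nqo1 -0.78 and for Hmox1 -0.80.

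Pericentral hepatocyte genes were higher in old livers as a group, with 20 of 20 tested members positive and a median difference of 1.33 (camera adjusted p = 5.34e-07). The call was not kept with an estimated correlation of 0.493 between members, at an adjusted p = 0.578 with an estimated correlation. Slc1a2 passed over all genes, and 10 members were higher adjusted over the list alone. Slc13a3 differed by 5.16 (SE 0.87, adjusted p = 0.0510), Lgr5, a receptor of Wnt-responsive cells, by 3.19 (adjusted p = 0.182), and Oat by 2.05 (adjusted p = 0.184). Slc13a3 and Lgr5 were each above background on 1 of the 4 young arrays, so the size of their differences rests mostly on signal not above background. Slc13a3 was past the threshold in 6 of 19 other settings (adjusted p from 0.0118 to 0.0471). The list mean, centred per gene, was -0.82 and -1.57 in young replicates 1 and 2 and -0.36 and -0.30 in young replicates 3 and 4, against -0.22 to 1.48 in old livers. Periportal genes did not pass (camera adjusted p = 0.937), but were past the threshold as lower in old livers with array weights (0.00303) and without young replicates 1 and 2 (0.000268), with Cdh1 at -3.93 (SE 0.86, adjusted p = 0.120; above background on 2 of the 4 old arrays).

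**Figure D2:**
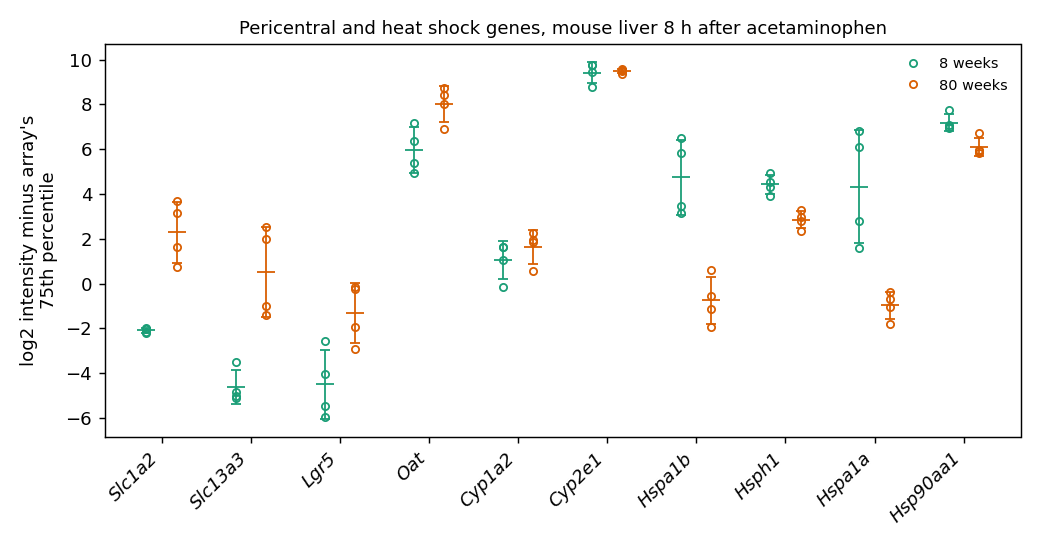
Log2 intensity minus each array's 75th percentile (vertical axis) for named pericentral and heat shock genes and for Cyp1a2 and Cyp2e1 (horizontal axis). Circles are single arrays, and bars show mean ± SD of 4 arrays at 8 weeks (green) and 80 weeks (orange). Slc1a2 is higher in every old array, Hspa1b is lower in every old array, and Cyp2e1 differs by 0.07.

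Heat shock response genes were lower in old livers as a group, with 15 of 18 tested members negative and a median of -0.77 (camera adjusted p = 5.34e-07, and adjusted p = 0.429 with an estimated correlation). Hspa1b passed over all genes, and adjusted over the list alone 10 members were lower and 1 higher. Hspa1a, a near-identical copy of Hspa1b, differed by -5.31 (SE 1.05, adjusted p = 0.0908), Hsph1 by -1.58 (adjusted p = 0.0559, but past the threshold in 5 of 20 other settings, from 0.0325 to 0.0489) and Hsp90aa1 by -1.08 (adjusted p = 0.164). Fry's directional test of this list gave an adjusted p = 0.0227. NRF2 target genes were lower by a median of -0.34, with 17 of 23 negative and 0 past the threshold (camera adjusted p = 0.00189, and adjusted p = 0.449 with an estimated correlation). Among them Akr1b8 differed by -1.84, Gsr by -0.66 and Txnrd1 by -1.05. Unfolded protein response genes were lower as a group (camera adjusted p = 0.0260, and 0.763 as the adjusted p with an estimated correlation), with Hyou1 at -0.82. This call was lost without young replicate 3 or 4 or old replicate 1 or 2. Without young replicates 1 and 2 together the camera adjusted p was 9.85e-08, so the result depended strongly on which arrays were kept.

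In lipogenesis and lipid droplets, 18 of 22 members were positive with a median of 0.92 (camera adjusted p = 9.21e-05, and adjusted p = 0.578 with an estimated correlation). Cidea passed over all genes, and 3 members were higher adjusted over the list alone. Srebf1, a transcription factor of lipid synthesis, differed by 1.29 (SE 0.33, adjusted p = 0.172), and Plin4 by 1.73, and Mogat1 showed a 4.01-fold ratio of old over young (adjusted p = 0.279). Cholesterol synthesis genes had a median of 0.32 (camera adjusted p = 0.0172, and adjusted p = 0.763 with an estimated correlation). This call was lost without young replicate 3 (adjusted p = 0.225) and with no filter on dim probes (0.0941). Without young replicates 1 and 2 together the camera adjusted p of the cholesterol list was 9.47e-06. PPAR-alpha and fatty acid oxidation genes had a median of 0.51 with 0 of 25 past the threshold (camera adjusted p = 0.00281, and adjusted p = 0.763 with an estimated correlation). Bile acid genes had a median of 0.41 with 19 of 19 positive (camera adjusted p = 0.00479, and adjusted p = 0.763 with an estimated correlation). Without young replicate 2 the fatty acid and bile acid calls were lost (adjusted p = 0.101 and 0.124), and without young replicates 1 and 2 their adjusted p was 0.952, in the opposite direction, and 0.762.

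MHC class II genes were higher in old livers, with 7 of 7 members positive and a median of 1.13 (camera adjusted p = 3.23e-06, and adjusted p = 0.578 with an estimated correlation), 6 of them higher adjusted over the list alone. H2-Eb1 differed by 1.40 (SE 0.31, adjusted p = 0.135) and H2-Ab1 by 1.40. Among B cell and plasma cell markers 6 were tested (camera adjusted p = 0.0157, and adjusted p = 0.609 with an estimated correlation), where Jchain passed. T cell and NK cell markers had a median of 0.22 (camera adjusted p = 0.0158, and adjusted p = 0.734 with an estimated correlation), with Cd2 at 1.22. Both lymphocyte calls were lost without young replicate 2 (adjusted p = 0.0935 and 0.112), that of T cell and NK cell markers also without old replicate 1 and with no filter on dim probes (0.142), and both without young replicates 1 and 2 together (0.310 and 0.0953). Adipocyte markers were higher (8 tested, camera adjusted p = 0.00819, and adjusted p = 0.429 with an estimated correlation), Cidea among them, with Cfd at 3.47 (SE 1.36, adjusted p = 0.324; above background on 1 of the 4 young arrays), and fry's directional adjusted p was 0.0227. That call was lost with no filter on dim probes (0.203) and with signal required on all arrays (0.199). Kupffer cell (0.196), monocyte (0.503), neutrophil (0.0608), endothelial (0.242), stellate (0.283), cholangiocyte (0.754), erythroid (0.161) and pancreatic acinar (0.0720) markers did not pass by camera adjusted p. The chemokine gene Ccl2 differed by -1.50 (SE 0.54, adjusted p = 0.305), Tnf by -0.71 and Il6 by 0.41.

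Circadian clock genes were higher in old livers, with 16 of 16 positive and a median of 0.52 (camera adjusted p = 0.000988, and adjusted p = 0.578 with an estimated correlation), and Cry2 differed by 1.27 (adjusted p = 0.168). Male-biased liver genes had a median of 0.34 (camera adjusted p = 0.00345, and adjusted p = 0.763 with an estimated correlation), with Susd4 past the threshold and Nudt7 at 2.56. Complement and coagulation genes had a median of 0.22 (camera adjusted p = 0.00479, and adjusted p = 0.763 with an estimated correlation). Cell cycle genes were lower, with 14 of 16 negative (camera adjusted p = 0.00517, and adjusted p = 0.578 with an estimated correlation), and Mcm6 differed by -1.24 and Mki67 by -0.23. Oncofetal genes were lower (camera adjusted p = 0.00978, and adjusted p = 0.593 with an estimated correlation), with Afp at -1.62. Regeneration signals were lower (camera adjusted p = 0.0489, and adjusted p = 0.593 with an estimated correlation), with Ereg at -2.22, and this call was lost under 5 of the 8 omissions of 1 array and under 7 other settings of processing (adjusted p from 0.0509 to 0.192). Without young replicate 2 the male-biased, complement and oncofetal calls were lost (adjusted p = 0.178, 0.283 and 0.178). Without young replicates 1 and 2 the adjusted p was 0.499 for male-biased, 0.748 for complement, 0.637 for cell cycle, 0.693 for oncofetal and 0.297 for regeneration lists. With array weights 9 of the 18 list calls were lost (adjusted p from 0.192 to 0.297), those of the B cell, T cell, complement, fatty acid, bile acid, male-biased, cell cycle, oncofetal and regeneration lists, and the oncofetal call also with signal required on all arrays (0.0504). Without young replicates 1 and 2 the difference of list means was over 1.5 times smaller, or turned, for 10 of the 18. Among them were lipogenesis (from 1.23 to 0.741) and circadian clock (from 0.666 to 0.362). The difference was larger in size for adipocyte markers (from 1.89 to 1.92), cholesterol synthesis (from 0.243 to 0.436) and the unfolded protein response (from -0.231 to -0.623). In all, 12 lists were higher and 6 lower by camera, 0 and 0 with an estimated correlation, and 1 and 1 by fry's directional test.

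**Figure D3:**
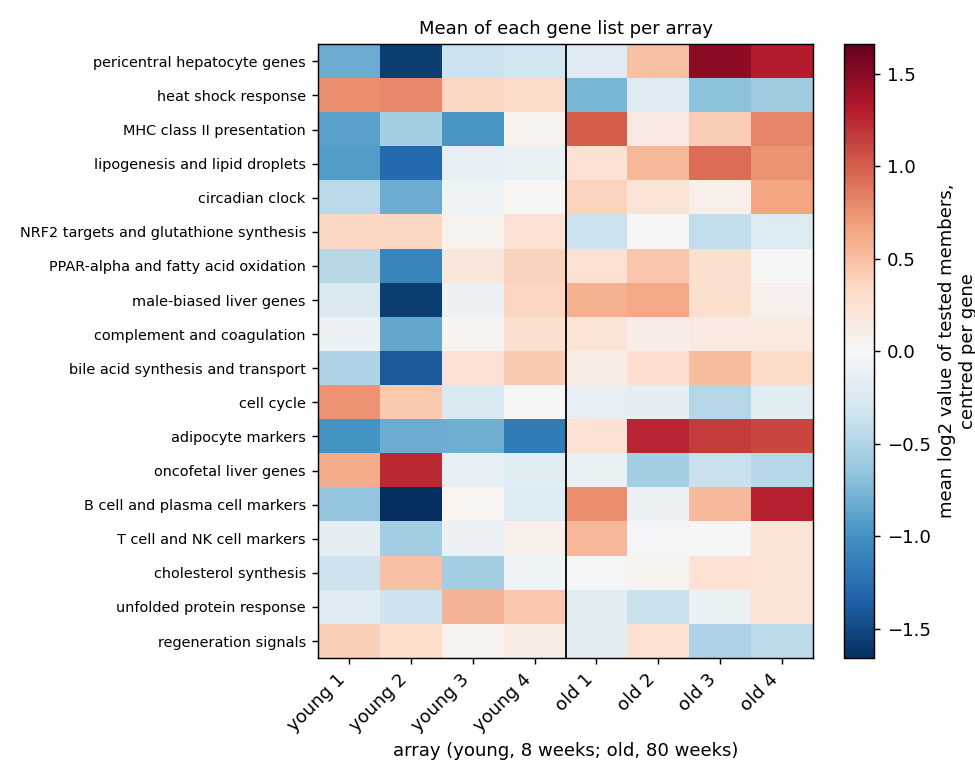
Mean log2 value of the tested members, centred per gene (colour scale), for the 18 lists past camera's threshold (vertical axis) on each of the 8 arrays (horizontal axis). Young replicate 2 has the lowest pericentral mean, -1.57, and old replicates 3 and 4 the highest, 1.48 and 1.30.

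The remaining lists did not pass by camera adjusted p. Core hepatocyte genes (0.418), oxidative phosphorylation (0.298), glucose metabolism (0.0517), autophagy and lysosome (0.0538), cytokines and chemokines (0.0538), extracellular matrix and fibrosis (0.100), p53 targets (0.196), cell death regulators (0.369), acute phase response (0.593), interferon response (0.741), immediate early genes (0.746) and senescence markers (0.830) were among them. Integrated stress response (0.549), female-biased (0.754), cholangiocyte and periportal lists had a median opposite in sign to the test. Oxidative phosphorylation was past the threshold in the opposite direction with array weights (0.00804) and without young replicates 1 and 2 (5.4e-06). Monocyte markers were so under the latter omission (0.0103). Some lists not past the threshold were past it in the same direction elsewhere, over 22 settings of processing, test or omission of 1 array. These were glucose metabolism in 12, autophagy and lysosome in 8, cytokines and chemokines in 8, extracellular matrix in 5, neutrophil in 4, endothelial in 3 and 8 further lists in 1 or 2, and with an estimated correlation no list was past it (lowest adjusted p = 0.429). Single members included Cdkn2a, a senescence marker, at 3.62 (SE 0.64, adjusted p = 0.0562; past the threshold in 3 of 19 other settings, from 0.011 to 0.0464; above background on 1 of the 4 young arrays), Chil3 at -3.73 (adjusted p = 0.117), Cdkn1a at 0.75, Atf3 at 0.30, Ddit3 at -0.46, Gclm at -0.31 and Hgf at 0.16.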

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

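The tests of pericentral and heat shock genes below were chosen after the values were seen, whereas the counts of splits for genes and lists were planned. Of 208 groups of 4 values examined, 11 held an array far from the other 3 (5.29%), and chance gives about 5%. The flags as a whole are thus no more than chance would give for 1 array apart from the other 3. The check cannot find 2 arrays that lie apart together, as young replicates 1 and 2 did on the first principal component. For Zfp979, not above background on any young array, young replicate 4 was at -5.19 against -4.34 to -4.25 in the other young arrays. For Susd4, young replicate 2 was at -0.733 against 0.456 to 0.601. For Scara5, old replicate 3 was at -1.70 against -0.28 to 0.0132. For Hsp90aa1, young replicate 1 was at 7.75 and old replicate 2 at 6.71, against highest other values of 7.06 and 5.98. For H2-Ab1, young replicate 4 was at 4.44 against at most 3.35. For Slc13a3, young replicate 2 was at -3.50 against at most -4.86. The mean of the cell cycle list was -0.473 in old replicate 3, and that of adipocyte markers 0.239 in old replicate 1. In young replicate 2 the mean of neutrophil markers was 0.759 and that of immediate early genes -0.510.

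The count of 58 genes higher in 80-week livers was reached by 1 of the 35 splits of the 8 arrays, the real one, and the highest other split gave 1. The count of 5 lower genes was also reached by 1 split, with 0 as the highest other. Counts at 2-fold gave the same numbers (1 split each). This argues against chance assignment of the arrays but cannot exclude it, since 1 of 35 is the smallest share these splits can give. Every other split also mixes the ages, which puts any age difference into the spread within groups and lowers its counts. For lower genes each other split was read in its lesser direction, so that comparison is the weaker. The size of the counts rests on single arrays, with 25 higher and 2 lower genes without young replicate 1, 3 lower without young replicate 2, 8 lower without young replicate 4, 14 lower without old replicate 2, 33 higher without old replicate 3 and 35 higher without old replicate 4. The lists differ from this. As many as 12 lists in one direction were reached by 15 of the 35 splits, with 18 in the highest other, and 6 in the lesser direction by 15, with 10 in the highest other, so chance cannot be excluded for the number of lists that camera called.

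By camera, pericentral genes were higher and heat shock genes lower in old livers, and neither call was kept with an estimated correlation (adjusted p = 0.578 and 0.429). These 2 lists were picked from 44 for their small p, so their differences of list means, 1.52 and 1.12, were each set against the largest difference of any list in the other splits. With the real one included, some list reached the first in 2 of 35 splits and the second in 11 (highest other 1.54). These differences were not scaled by each list's spread, so lists with a wide spread can set the bar, and this comparison cannot decide. Within its own list the highest other split was 1.48 for pericentral and 0.853 for heat shock genes, below the real one. Since both lists were picked for their small p, chance cannot be excluded for either. Scaling and background correction as the whole cause are argued against, since over normexp and quantile scaling the difference that was smallest against its SE was 1.16 (SE 0.42) for pericentral and -1.08 (SE 0.25) for heat shock genes. Without young replicates 1 and 2 the heat shock difference was -0.89 (SE 0.18), which argues against those arrays alone for this list mean. That mean counts the near-identical copies Hspa1a (-5.31) and Hspa1b (-5.50) separately among its 18 members, whose median was -0.77. Both weigh heavily in the heat shock differences given here, which were not computed without them. Without the same arrays the pericentral difference was 1.09 (SE 0.59). It cannot be told apart from the effect of those arrays, since it is under 2 SE with 2 young arrays left. Age, the slide row and an unequal extent of injury between samples may each contribute, and none of them was tested.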

How the results depend on the processing

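One setting, leaving out young replicates 1 and 2 together, was chosen after the data were seen. All 63 called genes kept their direction under every setting that tested them. The groups did not overlap for any of the 63, so leaving out or weighting arrays could not have turned a direction. For those settings the kept direction is thus no sign of stability. The cause of each change below was not tested unless stated. The 58 higher and 5 lower genes became 57 and 8 with quantile scaling, 64 and 13 with median scaling, 72 and 8 with no filter, 65 and 9 with the mean of a gene's probes, and 63 and 8 with a trended, robust prior, and the counts at 2-fold were the same in these settings. Requiring background-exceeding signal on all 8 arrays gave 20 and 1, also at 2-fold, and left 24 of the 63 calls to be tested. Normexp gave 41 and 4 with 33 of the 63 calls kept, or 45 and 5 with quantile scaling and 39 kept. Zfp979, Scara5, Igsf21, Bex1 and Ces1a lost the call under both and Mmd2 and Reep1 under the first (adjusted p from 0.0526 to 0.332). Their log2 differences were 2.3 to 5.2 times smaller, and each of these genes was above background on no array of one group. The offset of 50 added with normexp by itself makes the differences of dim genes smaller. Array weights gave 136 and 36 (126 and 29 at 2-fold). The authors' deposited table and retained outlier spots each gave 58 and 5. With 1 array left out, the higher count ran from 25 to 69 and the lower from 2 to 14, also at 2-fold, and without young replicates 1 and 2 the counts were 12 and 2, also at 2-fold, with 11 of the 63 calls kept in a smaller sample. For lists, 12 higher and 6 lower became 0 and 0 with an estimated correlation and 1 and 1 with fry, 12 were lower with no filter, 6 were higher with array weights, 7 were higher without young replicates 1 and 2, and with 1 array left out the higher ran from 6 to 18 and the lower from 4 to 10. With the replicate block, 53 genes were higher and 17 lower, also at 2-fold, and 41 of the 63 calls were kept. Zfp979 (adjusted p = 0.0511), Scara5 (0.0896) and Reep1 (0.067) were no longer called, and Lgr5 (0.0339), Cdh1 (0.0213) and Ereg (0.0416) were. The replicate number is also the slide column, so the block covers both. The numbers were not taken to pair the samples, since deviations of same-numbered samples correlated at 0.026, 0.14, 0.11 and 0.10, although young replicates 2, 3 and 4 matched the old array of their own number best and only young replicate 1 matched another, old replicate 2. Slide and scan could not be blocked, with 1 of each. Some values that did not pass turned sign. Cyp2e1 was -0.0299 with median scaling, -0.184 with array weights and -0.25 without young replicates 1 and 2, and ran from -0.147 to 0.183 with 1 array left out. Hgf was -0.00125 with normexp and ran from -0.147 to 0.395. Mki67 was 0.752 with array weights and 1.19 without young replicates 1 and 2, and ran from -0.842 to 0.495. Atf3 was -0.0952 without young replicates 1 and 2. With 1 array left out, Cyp3a11 ran from -0.546 to 0.264, Ddit3 from -1.12 to 0.171 and Il6 from -0.0844 to 0.967. Lists whose direction turned are given by adjusted p. With array weights these were immediate early, cell death, acute phase and cholangiocyte (0.742 each), monocyte (0.199), erythroid (0.594), core hepatocyte (0.15), female-biased (0.977) and oxidative phosphorylation (0.00804). Without young replicates 1 and 2 they were bioactivation and immediate early (0.762 each), cell death and female-biased (0.549 each), acute phase and cholangiocyte (0.642 each), monocyte (0.0103), erythroid (0.66), core hepatocyte (0.0594), fatty acid oxidation (0.952) and oxidative phosphorylation (5.4e-06). With no filter they were immediate early (0.498), senescence (0.423) and acute phase (0.787). With signal on all arrays they were integrated stress (0.955), senescence (0.934) and periportal (0.717). With the mean of probes they were senescence (0.933) and cholangiocyte (0.854), with the replicate block immediate early and senescence (0.927 each), with median scaling periportal (0.903) and with fry periportal (0.993). With 1 array left out, lists that turned ran from 0.0765 to 0.952 for bioactivation, 0.278 to 0.983 for immediate early, 0.458 to 0.919 for senescence, 0.275 to 0.838 for acute phase, 0.0438 to 0.98 for interferon, 0.0417 to 0.983 for Kupffer, 0.156 to 0.785 for monocyte, 0.549 to 0.972 for cholangiocyte, 0.223 to 0.969 for periportal, 0.156 to 0.983 for core hepatocyte, 0.0258 to 0.54 for oxidative phosphorylation and 0.136 to 0.972 for female-biased. Signal over background limits 24 called genes, which were above background on no array of one group.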

Other observations

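The tests below on probe sequence, strain and fat were chosen after the values were seen. The test of gene positions was set before its result was known, but its prediction already named the chromosomes given below. Neighbouring called genes may thus have been seen first, and its permutation p may then test a pattern taken from the same calls. Of 24 tested probes whose description names an immunoglobulin chain, a set put together after the values were seen, 9 passed the threshold as higher in old livers and 15 did not. All 24 differences were positive, from 0.108 to 5.60, with a median of 2.70, or 1.67 with the 9 probes above background on no young array at their bound. Those 9 probes passed the filter on dim probes only through the old arrays, so the filter itself favoured a positive sign for them. The mu heavy-chain constant region differed by 5.60 (SE 0.48, adjusted p = 0.00183), although a second mu probe differed by only 0.80 (adjusted p = 0.368), and the kappa constant region by 3.23 (SE 0.48, adjusted p = 0.0249), and 6 kappa variable segments passed. Some of these segments share probe sequence and are not independent. Blood carried over in larger amounts would bring erythroid transcripts, whose list had a median of -0.88, not past the threshold. The erythroid list means were 0.359 (SD 0.954) in young and -0.359 (SD 0.933) in old livers. The direction turned without young replicates 1 and 2 and with array weights, so this list does not decide whether blood contributed.

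Genes past the threshold lay close together. Of 63 called genes, 20 had another within 500 kb, where 10000 random draws of as many tested genes had a median of 2 and a highest value of 16, a permutation p of 1e-04, the smallest these draws can give. Leaving out genes whose description names immunoglobulin, 12 of 52 had such a neighbour (highest draw 12, permutation p = 6e-04). One group lies on chromosome 1 between 85038372 and 85305128 (mm9), with 5 higher genes that include A530032D15Rik (at least 2.02-fold higher, adjusted p = 0.0274) and Gm7609 (at least 1.81-fold higher, adjusted p = 0.00946). Another lies on chromosome 4 between 146887459 and 146986112, with the zinc finger genes Zfp982 and Zfp985 (log2 differences of 3.09 and 2.89, the latter above background on 2 of 4 young arrays) and Zfp979 (at least 8.41-fold higher). Shared probe sequence is argued against, since 0 of these 8 probes share a run of 20 bases with another, although cross-hybridisation to a further family member was not tested. A strain or copy-number difference between the age groups cannot be told apart from age, because no strain was given, and 4 of the 8 were above background on no young array. A local change with age may also be considered and was not tested.

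Cidea was higher in old livers, and so by camera was the adipocyte marker list, in which only Cidea of 8 tested members passed. That call was not kept by camera with an estimated correlation (adjusted p = 0.429). The estimate for this list was -0.00207, below the preset 0.01, so correlation between its own members does not explain the loss. Whether fat tissue in the samples contributed cannot be told apart from a change in the liver itself. Fabp4 and Plin1, abundant in fat, differed by -0.52 (SE 0.27) and 0.10 (SE 0.48), and the higher of the pair plus 2 SE reached 1.05, below the 8.97 of Cidea. Fabp4 was above background on 4 arrays of each group, so its level in all samples could hide a small share of fat, and Plin1 lay near background. Of the 7 other tested markers, 3 were higher by more than 2 SE (Cfd by 3.47, Cidec by 1.02 and Adrb3 by 1.01, none past the threshold). Fabp4 and Plin1 fall outside the naming rule and were chosen for this test after their values were seen.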
